A study of Sus scrofa with 20 samples.

How the data were processed

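Gene expression was measured with single-colour arrays in 20 biopsies of the proximal colon of 10 pigs, 1 biopsy per pig and diet. Per the labels' protocols, total RNA was extracted with TRIzol and columns, its integrity was checked by chip electrophoresis, and whole-transcript complementary DNA was labelled with biotin for hybridization. The deposited values are log2 intensities that the authors obtained with RMA (robust multi-array averaging, which corrects background, quantile-normalizes the arrays and summarises the probes of a set), per the submitters' processing notes. The version of the software, the probe-set definition and any filter are not given in the sources used here. The array medians lay between 5.67 and 5.75 on this log2 scale. Because RMA brings all arrays to one distribution, a change in total RNA per cell is not visible, and a gain of one tissue component shows as a loss of the others. RMA also compresses differences at low intensity.

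The table held 27558 rows. Gene names came from the platform annotation given for these rows: 13323 rows had 1 gene symbol, 357 had several and were left unnamed, and 13878 were not listed there and are unnamed here. Symbols were updated through gene identifiers against a RefSeq table of assembly Sscrofa11.1, which altered 7 symbols and was used for names only. Where a gene had several rows, which was the case for 902 genes, the row with the highest mean over all 20 arrays stood for it. Control rows could not be told from other unnamed rows and stayed in. This left 26596 features, 12361 of them with a gene name. The median over rows of the mean log2 level was 6.19 for named and 5.24 for unnamed rows. No filter on dim rows was applied in the main setting.

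Diet, period and pig came from the labels. Each pig served as its own control in a crossover, with 5 pigs given digestible starch first and 5 given resistant starch first. The main model was fitted per feature with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with pig as a block, period (2 against 1) and diet as terms. Changes are log2 differences, resistant minus digestible starch or period 2 minus period 1, with their standard errors. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all features, with a threshold of 0.05. The diet order was tested with limma on each pig's mean over its 2 arrays, 5 pigs against 5. In a crossover this contrast also holds carry-over from the first diet and a diet effect that differs between periods, which it cannot tell apart. The number of arrays limits the precision, and the median standard error of a diet change was 0.09.

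The pairing comes from the labels, which name the pig of each biopsy. It was checked in the values. After removal of diet and period means, the correlation between a pig's 2 arrays ranged from -0.0689 to 0.386 with a median of 0.254, was over 0.1 in 8 of the 10 pigs, and was lowest in pigs 5 and 6. By these correlations 13 of the 20 arrays stood closest to the other array of their own pig and 7 to an array of another pig. In 11 rows the levels fell into 2 clusters separated by more than 0.8 and by more than 2 times the larger SD within a cluster, limits set after the data were seen. For all 20 arrays the other array of the same pig shared the cluster in as many of these rows as any other array or more, with 2 ties.

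Gene lists for pathways and for the cell types a colonic biopsy can hold were fixed before the data were examined, as were the models, the alternatives and the rule for the genes named; alternatives and tests chosen later are said to be so where they are given. The 42 lists held 1198 genes, of which 773 were measured here; 41 lists had the minimum of 5 measured members. Members were matched by symbol, with 5 matched through a synonym. Another 5 synonym matches pointed to a different gene and were set aside, a review made after list results had been seen once. Lists were tested with camera in limma, which compares the members with all other features, at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Beside it stand camera with a correlation estimated per list, and fry, which tests whether the members on balance move one way without comparing them with other genes. Exact sign flips of each pig's change in the list mean (1024 flips, smallest possible p = 0.00195) were added after the data were seen. Counts of members are given over all genes and adjusted over the list alone. PPARGC1A, fixed in advance, and the ketone body list were not analysed here, because they had no named row or too few of them.

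Genes were named by a fixed rule. For diet these were the 12 with the largest change in each direction among those past the threshold, filled up by the smallest unadjusted p where fewer than 12 passed. Added to these were up to 4 members of each called list with the smallest p in its direction, and a few genes of short-chain fatty acid transport and PPAR signalling whatever their values. For period 5 in each direction were taken in the same way.

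The procedure was tested on simulated data made from the diet comparison's own means and residual spreads over 26596 features, with residuals drawn independently between genes. Of the genes changed by 0.5 on the log2 scale 61% were recovered, and of those changed by 1 95%; 6 of 163 calls were false. All 5 lists shifted by 0.2 were called, and so was 1 of 33 unshifted lists. The simulation holds no correlation between genes, so it does not show how many lists are called by chance where the members of a list vary together; camera called a median of 13 lists when diet was relabelled within pigs.

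Alternatives covered the pig term (left out, or as a random effect), period left out, an intensity trend or robust variance prior, filters on dim and on stable rows, median centring, quantile and cyclic loess normalization, array weights, the mean of all rows of a gene, smooth muscle and fibroblast list means as covariates, each period alone, and leaving out each pig in turn.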

Results

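Biopsies of the proximal colon were taken from 10 castrated male Landrace pigs through a cannula, at the end of each of 2 diet periods of 14 days. One diet contained digestible starch, which is absorbed in the small intestine, and the other resistant starch, which reaches the colon and is fermented there to short-chain fatty acids. Every pig ate both diets, 5 in each order, and was 22 weeks old at the first biopsy and 24 weeks old at the second. The 20 arrays gave 10 biopsies per diet, and all values below are log2 intensities unless stated otherwise.

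The comparison of diets asked how metabolic, immune and cell division genes of the colon tissue differed within pigs between resistant and digestible starch. On resistant starch, markers of surface colonocytes, the absorptive cells at the top of the crypt, rose as a list by a mean of 0.31 ± 0.21 (SD over 10 pigs), and lists of fatty acid oxidation, the TCA cycle and ion transport rose with them. Lists of T cells, B cells, antigen presentation and antimicrobial defence fell. These calls compare each list with all other genes by camera at a preset correlation, and none of them held with an estimated correlation, where the smallest adjusted p was 0.143. SLC16A1, a transporter of lactate and butyrate, was at 11.19 ± 0.27 (SD, n = 10) on resistant and 10.56 ± 0.40 on digestible starch. The means differed 1.54-fold and the level was higher in 10 of 10 pigs. The gene did not pass the threshold over all genes (limma, adjusted p = 0.176).

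No single feature passed the adjusted threshold. limma called 0 of 26596 features, with a smallest adjusted p of 0.106, while 2643 features had an unadjusted p under 0.05 where 1330 were expected by chance, 1499 of them higher and 1144 lower on resistant starch. Among the 12361 features with a gene name, 1379 had an unadjusted p under 0.05 against 618 expected. With pig as a random effect, 6 features passed, among them TMPRSS2 and USH1C, each with an adjusted p of 0.0322. In period 1 alone, a comparison between 5 and 5 pigs, limma called 2 features, CHI3L1 (adjusted p = 0.0294) and PLEKHG6 (adjusted p = 0.0405).

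Of the 12 genes with the smallest unadjusted p and a higher level on resistant starch, none passed the threshold. TMPRSS2, a transmembrane serine protease, was at 9.38 ± 0.26 (SD, n = 10) on digestible and 9.92 ± 0.16 on resistant starch, a change of 0.54 with a standard error of 0.08 (limma, adjusted p = 0.106). SCNN1A, the alpha subunit of the epithelial sodium channel, differed by 0.50 ± 0.07 (SE), SLC9A2, a sodium-hydrogen exchanger, by 0.43 ± 0.07, and USH1C, a protein of the microvillus tip, by 0.41 ± 0.07. GUCA2B, the precursor of uroguanylin, was 2.01-fold higher and SLC30A10, a metal ion exporter, 1.91-fold higher. Genes of lipid and mitochondrial metabolism in this group were ACSF2, an acyl-CoA synthetase (change 0.50), AGPAT2, an enzyme of phosphatidic acid synthesis (0.34), and UCP3, a mitochondrial carrier (0.36). SEMA6A (0.43), SCUBE1 (0.40) and PLEKHG6 (0.56) completed the 12. All were higher in 10 of 10 pigs, except SLC30A10, which was higher in 9, and their adjusted p-values lay between 0.106 and 0.155.

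The 12 genes with the smallest unadjusted p and a lower level on resistant starch did not pass the threshold either. CHI3L1, a chitinase-like secreted protein, was at 8.65 ± 1.45 (SD, n = 10) on digestible and 6.79 ± 0.60 on resistant starch. Its change was -1.86 ± 0.27 (SE, limma adjusted p = 0.106). Its period change was -0.88 ± 0.27 (SE, limma adjusted p = 0.999), and between pigs in period 1 alone the diet estimate was -3.06. The protease inhibitors SLPI and PI3 differed by -1.11 and -0.46 and were lower in 10 of 10 pigs; the 2 rows of SLPI held the same values. CXCR4, a chemokine receptor of lymphocytes, differed by -0.75 ± 0.13, CCL28, a chemokine of mucosal epithelium, by -0.47 ± 0.08, and LEF1, a transcription factor of T cells and Wnt signalling, by -0.72 ± 0.15. SLAMF1 (-0.42), a receptor of lymphocytes, NUGGC (-0.52), PARVG (-0.52), TMEM156 (-0.66), PCD1B (-0.60) and PHF19 (-0.30) made up the rest. Each was lower in at least 8 of 10 pigs, and adjusted p-values reached 0.2.

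**Figure D1:**
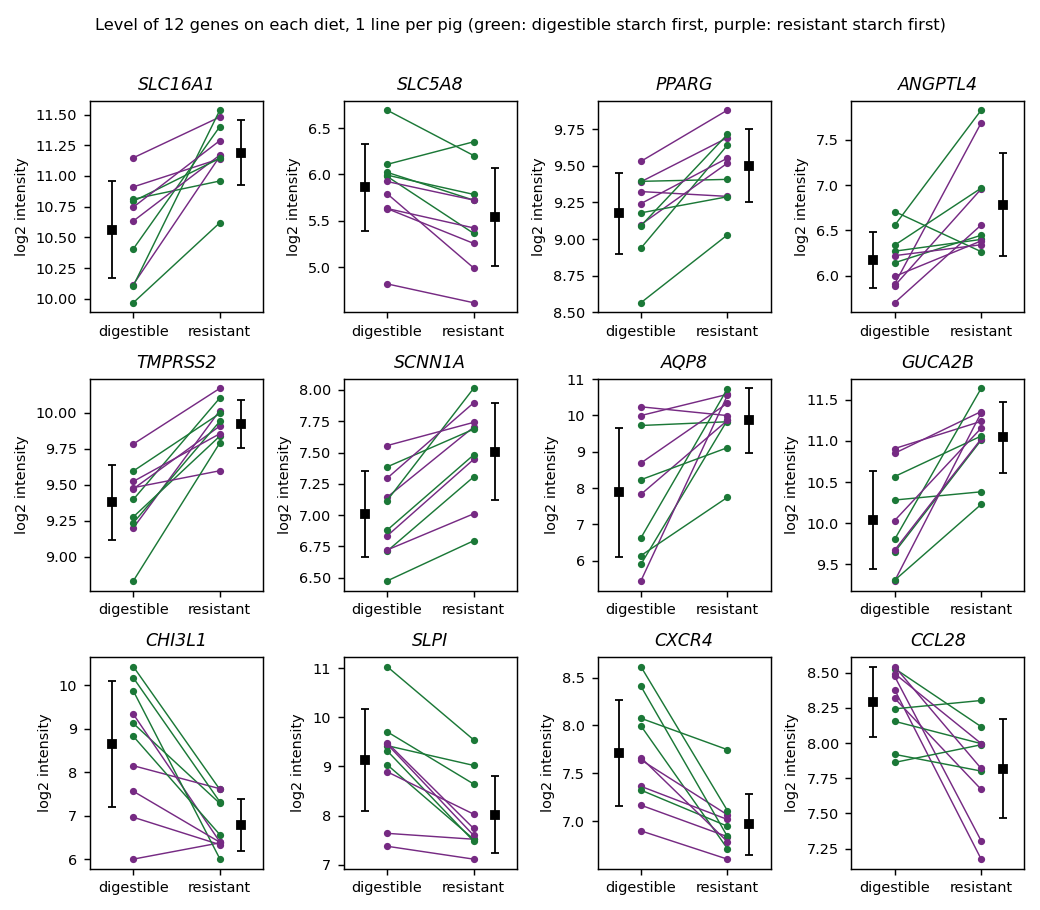
Level of 12 genes in each pig's 2 biopsies (y axis, log2 intensity) on digestible and resistant starch, with 1 line per pig coloured by diet order and squares with bars for the mean and SD of 10 pigs. SLC16A1 was higher on resistant starch in 10 of 10 pigs and SLC5A8 in 1 of 10, while CHI3L1 went from a mean of 8.65 to 6.79; none of the 12 genes passed the adjusted threshold in limma.

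Of the 41 gene lists, camera called 25 for diet, 10 higher and 15 lower on resistant starch. With an estimated correlation the count was 0, with 5 lists at an unadjusted p under 0.05, and fry called 1, the surface colonocyte list (adjusted p = 0.0246). Exact sign flips of each pig's change, added after the data were seen, called 4 lists, those of surface colonocytes, of ion and water transport, of nuclear receptors and of short-chain fatty acid transport, each with an adjusted p of 0.04. Of the 25 calls 17 held when each pig was left out in turn.

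Surface colonocyte markers formed the group with the most members past a test. Of 20 measured members 11 rose and 1 fell adjusted over the list alone, against 0 over all genes, and the list mean was higher in 9 of 10 pigs (camera adjusted p = 5.14e-08). With an estimated correlation the adjusted p was 0.143. GUCA2A, the precursor of guanylin, rose by 0.67 ± 0.17 (SE), GUCA2B by 1.01 ± 0.19, VIL1, the microvillus protein villin, by 0.35 ± 0.09 and SLC9A2 by 0.43 ± 0.07. The member that fell was PLAC8, by 0.76. Ion and water transport genes rose as a list by 0.20 ± 0.17 (SD over 10 pigs; camera adjusted p = 0.00258, adjusted p = 0.325 with an estimated correlation), with 3 of 18 members past the threshold adjusted over the list alone: SCNN1A, SLC9A2 and the water channel AQP8. SLC9A2 and AQP8 also belong to the surface colonocyte list, so the 2 lists are not independent. AQP8 was at 7.88 ± 1.78 (SD, n = 10) on digestible and 9.86 ± 0.88 on resistant starch. The means differed 3.94-fold, and AQP8 was higher in 9 of 10 pigs. The largest rises were in pigs 1, 5 and 6, from 5.90, 5.45 and 6.63 to 9.87, 10.55 and 10.73. Pig 4 went from 9.72 to 9.82, and pig 3 fell from 10.24 to 9.99. The chloride channel CFTR differed by 0.22 ± 0.08 (SE). Tight junction and adhesion genes rose by 0.12 ± 0.17 (SD over pigs; camera adjusted p = 0.00246, adjusted p = 0.325 with an estimated correlation). CLDN2, a claudin of cation-permeable junctions, was the 1 member of 17 past the threshold adjusted over the list alone (0.42 ± 0.10, SE), beside CLDN7 at 0.21, CGN at 0.15 and CLDN4 at 0.41 (0.24 without pig 5). CLDN7 also belongs to the surface colonocyte list, so these lists are not independent either. Between pigs in period 2 alone, the CLDN2 estimate was -0.12 and that of CGN -0.0048. In period 2 alone the 3 lists were not called, with adjusted p-values of 0.085, 0.085 and 0.504. The ion and water transport list was not called in period 1 alone either (camera adjusted p = 0.0515).

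Among lists of energy metabolism, fatty acid beta-oxidation genes rose by 0.14 ± 0.15 (SD over 10 pigs), in 9 of 10 pigs (camera adjusted p = 8.19e-05, adjusted p = 0.325 with an estimated correlation), although 0 of 18 members passed adjusted over the list alone. Its leading members were ACAD11 (0.56), ACADM, the medium-chain acyl-CoA dehydrogenase (0.22), CPT1A, which admits long-chain fatty acids to mitochondria (0.21), and the carnitine carrier SLC25A20 (0.29). PPAR target genes rose by 0.14 ± 0.19, in 8 of 10 pigs (camera adjusted p = 0.000477, adjusted p = 0.221 with an estimated correlation). In that list 1 of 24 members, TXNIP, passed adjusted over the list alone (0.29 ± 0.07, SE). ACADM, CPT1A, SLC25A20, ACAA2 and HADHA belong to both lists, so the 2 rises are not independent. TCA cycle genes rose by 0.10 ± 0.12 (camera adjusted p = 0.00198, adjusted p = 0.325 with an estimated correlation), with SUCLG2 at 0.22 (0.14 without pig 6), SUCLG1 at 0.14, DLD at 0.14 (0.095 without pig 6) and DLST at 0.13. Nuclear receptors of lipid metabolism rose by 0.13 ± 0.11 (camera adjusted p = 0.00403, adjusted p = 0.325 with an estimated correlation), with 2 of 14 members past the threshold adjusted over the list alone. These were NR1H4, the bile acid receptor (0.51 ± 0.12, SE), and PPARG (0.33 ± 0.08, SE); PPARGC1B stood at 0.15 and HNF4A at 0.18. Oxidative phosphorylation genes were not called, with a mean change of 0.04 ± 0.17 (SD over pigs; camera adjusted p = 0.153), nor were genes of glycolysis (-0.01 ± 0.10, adjusted p = 0.272). The first mean was -0.0030 without pig 6 and 0.070 without pig 5, and the second 0.020 without pig 9. In period 2 alone the calls for beta-oxidation, the TCA cycle and nuclear receptors ended, with adjusted p-values of 0.267, 0.108 and 0.527.

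Amino acid catabolism (0.12 ± 0.20, SD over 10 pigs) and xenobiotic and antioxidant enzymes (0.10 ± 0.17) also rose as lists, with camera adjusted p-values of 0.0049 and 0.018. Their adjusted p-values with an estimated correlation were 0.476 and 0.325. ACADSB, a dehydrogenase of isoleucine breakdown, was the 1 of 20 catabolic members past the threshold adjusted over the list alone (0.42 ± 0.10, SE), beside BCKDHA at 0.19, PCCB at 0.19 and ALDH6A1 at 0.27 (0.17 without pig 6, and -0.0027 between pigs in period 2 alone). The thioredoxin reductase TXNRD1 (0.22), the peroxiredoxin PRDX6 (0.44) and the glucuronosyltransferase UGT1A6 (0.19) passed among 20 members of the other list. GCLM stood at 0.22. In that list 12 members had a positive and 8 a negative change. The first call ended without pig 6 (mean change 0.067, adjusted p = 0.181). The second ended without pig 3 (0.087) or pig 6 (0.0848), with pig as a random effect (0.0748) and with no pig term (0.0822). Muscle and fibroblast covariates ended both calls (0.119 and 0.0567), and so did period 1 alone (0.0515 and 0.875). The first call also ended in period 2 alone (0.101) and with pigs 5 and 6 left out (0.0901).

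Genes tied to short-chain fatty acids were not called as a list by camera over both periods, with a mean change of 0.18 ± 0.12 (SD over 10 pigs) that was positive in 10 of 10 pigs (camera adjusted p = 0.239). In period 2 alone the list was called higher (median change 0.23, adjusted p = 0.0125). Over both periods the median change of its 8 members was 0.068, under the mean, with 5 members positive and 3 negative. Of the 8 members 2 rose and 1 fell adjusted over the list alone. SLC16A1 rose by 0.63 ± 0.12 (SE) and ABCG2, an efflux transporter, by 1.03 ± 0.28, while SLC5A8, a sodium-coupled transporter of butyrate, fell by 0.32 and was lower in 9 of 10 pigs. The second row of SLC5A8 gave a change of -0.57. SLC16A1 rose most in pigs 1, 5 and 6, from 10.41, 10.12 and 10.11 to 11.40, 11.16 and 11.54. Surface colonocyte markers rose most in the same pigs (0.54, 0.65 and 0.50). The share of surface epithelium was not measured, so it cannot be told apart from a change in the transporter itself. Between pigs, the SLC5A8 estimate was -0.96 in period 1 alone (limma, adjusted p = 0.202) and 0.33 in period 2 alone (adjusted p = 0.999). Of the other genes fixed in advance, ANGPTL4, a lipoprotein lipase inhibitor and PPAR target, stood at 0.61 ± 0.17 (limma, adjusted p = 0.272), PLIN2, a lipid droplet protein, at 0.18 ± 0.07 (adjusted p = 0.44) and PPARA at 0.06 ± 0.09 (adjusted p = 0.888; mean -0.0097 without pig 1, 0.031 without pig 5, 0.12 without pig 7 and 0.035 without pig 9). Between pigs, PLIN2 stood at -0.060 in period 1 alone and 0.42 in period 2 alone, PPARA at 0.26 and -0.15, and PPARG at 0.55 and 0.099.

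Lymphocyte markers were lower on resistant starch. T cell and NK cell markers fell by a mean of 0.28 on the log2 scale with an SD of 0.48 over 10 pigs, and the list was lower in 7 of 10 pigs (camera adjusted p = 4.41e-10, adjusted p = 0.325 with an estimated correlation). Without pig 1 the mean change was -0.17. Of 33 members 31 had a negative change, and 3 fell adjusted over the list alone: IL2RG, the shared cytokine receptor chain, by 0.58, the co-receptor CD27 by 0.36 and SLAMF6 by 0.55; CD5 stood at -0.32. B cell and plasma cell markers fell by 0.23 with an SD of 0.24, in 8 of 10 pigs (camera adjusted p = 1.16e-07, adjusted p = 0.207 with an estimated correlation). The members past the threshold adjusted over the list alone were the B cell receptor chains CD79A and CD79B and the kinase BTK, which fell by 0.47, 0.41 and 0.30, and CXCR5, the homing receptor of follicles, stood at -0.63 (-0.40 without pig 4). In the same biopsies smooth muscle markers stood at 0.19 ± 0.65 and surface colonocyte markers at 0.31 ± 0.21 (SD over pigs).

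Antigen presentation, interferon and inflammatory lists fell as well. The MHC class II antigen presentation list fell by 0.25 with an SD of 0.40 over 10 pigs (camera adjusted p = 3.03e-07). With an estimated correlation the adjusted p was 0.325. This list also holds genes other than MHC class II, such as CCR7 and CD83. All 17 members had a negative change, 6 of them with an unadjusted p under 0.05 in limma. Pigs 1 and 5 fell most (-0.99 and -0.82), and the list was lower in 8 of 10 pigs. The 1 member of 17 past the threshold adjusted over the list alone was CCR7, a homing receptor of dendritic cells and T cells (-0.51 ± 0.11, SE); SLA-DRB1 stood at -0.42, RFX5 at -0.28 and CD83 at -0.32. Interferon-stimulated genes fell by 0.31 with an SD of 0.49 (camera adjusted p = 3.92e-06, adjusted p = 0.325 with an estimated correlation), with 0 of 30 members past the threshold adjusted over the list alone. IDO1 stood at -0.94 ± 0.41 (SE), IFIT1 at -0.53 ± 0.23 (-0.31 without pig 6 and -0.34 without pig 9), OAS2 at -0.51 ± 0.21 and TRIM21 at -0.21 ± 0.09. Cytokines and chemokines fell by 0.24 with an SD of 0.37 (camera adjusted p = 4.19e-06, adjusted p = 0.325 with an estimated correlation), where CCL28 was the 1 of 39 members past the threshold adjusted over the list alone and IL6, IL10 and CXCL14 stood at -0.73, -0.43 and -0.26. Without pig 6 the mean change was -0.15 for the cytokine list and -0.46 for IL6. IL6 was dim, at a mean of 4.47 on digestible and 3.74 on resistant starch. It was lower in 9 of 10 pigs, and pig 9 went from 5.93 to 3.67. Between pigs, CXCL14 stood at 0.024 and CD14, a macrophage marker, at 0.014 in period 2 alone. Macrophage markers (-0.17 ± 0.31, SD over pigs) and genes of innate sensing and NF-kB signalling (-0.17 ± 0.24) fell with camera adjusted p-values of 0.000165 and 0.000244. Both had an adjusted p of 0.325 with an estimated correlation and 0 members past the threshold adjusted over the list alone. The macrophage call ended in period 2 alone (adjusted p = 0.0956). Pigs 1, 5 and 6 fell most, by -0.62, -0.54 and -0.48 for macrophages and -0.33, -0.40 and -0.65 for innate sensing. In these pigs surface colonocyte markers rose most (0.54, 0.65 and 0.50). The 2 lists were each lower in 7 of 10 pigs and share CD14, so they are not independent. Their leading members included SPI1 (-0.38), FCER1G (-0.34), TYROBP (-0.27) and CD14 (-0.27, or -0.18 without pig 6) for macrophages, and CLEC7A (-0.80), LY96 (-0.51), NFKB1 (-0.25) and TLR2 (-0.25) for innate sensing; a dim second row of TLR2 gave 0.02. MHC class I genes fell by 0.12 with an SD of 0.32 (camera adjusted p = 0.000701, adjusted p = 0.492 with an estimated correlation), were lower in 5 of 10 pigs, and lost the call without pig 5 (mean change -0.056, adjusted p = 0.0724); without pig 1 the mean change was -0.080. TAPBPL stood at -0.23, SLA-7 at -0.27, ERAP2 at -0.30 and PDIA3 at -0.15, the last 2 at -0.17 and -0.092 without pig 5, and SLA-7 at 0.0045 between pigs in period 1 alone.

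Antimicrobial and host defence genes fell by 0.34 with an SD of 0.32 over 10 pigs, in 9 of 10 pigs (camera adjusted p = 1.44e-07, adjusted p = 0.143 with an estimated correlation). Of 15 members 6 fell adjusted over the list alone. They were SLPI, PI3, the siderophore-binding LCN2 (-0.47), the hydrogen peroxide-producing oxidase DUOX2 (-0.40), its maturation factor DUOXA2 (-0.51) and TGM2 (-0.52). In period 2 alone the list was not called (adjusted p = 0.143). Genes of endoplasmic reticulum stress and protein folding fell by 0.14 with an SD of 0.23 (camera adjusted p = 3.92e-06, adjusted p = 0.325 with an estimated correlation), with EDEM1 the 1 of 22 members past the threshold adjusted over the list alone (-0.34 ± 0.08, SE) and CRELD2, PDIA4 and PDIA6 at -0.37, -0.29 and -0.25. In period 2 alone this call ended too (median change -0.0029, adjusted p = 0.975), and camera's direction was reversed. Complement genes fell by 0.12 with an SD of 0.22 (camera adjusted p = 0.00966, adjusted p = 0.391 with an estimated correlation). C4A fell by 0.56 and was lower in 10 of 10 pigs, while CD55, C1R and SERPING1 stood at -0.27, -0.28 and -0.26. Of the 16 complement members 9 had a negative and 7 a positive change. Without pig 5 the mean change was -0.067 for the list and -0.17 for SERPING1; the call ended without pig 1 (adjusted p = 0.165), pig 4 (0.0594) or pig 5 (0.0682).

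Cell cycle lists showed small shifts. DNA replication genes fell by 0.08 with an SD of 0.16 over 10 pigs, in 8 of 10 pigs (camera adjusted p = 0.000642, adjusted p = 0.391 with an estimated correlation). Genes of cell division fell by 0.09 with an SD of 0.33 and were lower in 6 of 10 pigs (camera adjusted p = 0.000724, adjusted p = 0.589 with an estimated correlation). In each list 0 members, of 29 and of 31, passed the threshold adjusted over the list alone. RFC3 (-0.33), CCNE2 (-0.23, or -0.14 without pig 1), GINS4 (-0.19) and POLA2 (-0.11) led the first list, and SMC4 (-0.27), TPX2 (-0.21), NDC80 (-0.20) and BUB3 (-0.10) the second. The mean change in cell division was -0.053, -0.030, -0.15 and -0.059 without pigs 1, 5, 6 and 9, and without pig 5 TPX2 stood at -0.13 and BUB3 at -0.060. The cell division call ended without pig 1 (adjusted p = 0.0622) or pig 5 (0.265), and the DNA replication call in period 2 alone (adjusted p = 0.811).

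Enteroendocrine and tuft cell markers fell by 0.13 with an SD of 0.24 over 10 pigs (camera adjusted p = 0.0245). With an estimated correlation the adjusted p was 0.496. Of 17 members 10 had a negative and 7 a positive change. TPH1, the enzyme of serotonin synthesis in enterochromaffin cells, was the 1 of 17 members past the threshold adjusted over the list alone (-0.78 ± 0.18, SE), beside PCSK1 at -0.54, CHGB at -0.53 and SCG5 at -0.12. That call ended without pig 2 (adjusted p = 0.086), pig 6 (0.275), pig 7 (0.0778) or pig 8 (0.0522). The list's median change, -0.031 over all pigs, was 0.028 without pig 6 (mean -0.070), 0.033 with muscle and fibroblast covariates and 0.0017 in period 2 alone. Smooth muscle markers were called higher (camera adjusted p = 0.0167, adjusted p = 0.632 with an estimated correlation), with KCNMB1 at 0.25, PLN at 0.49, MYL9 at 0.36 and HSPB6 at 0.24. They were higher in 5 of 10 pigs, with pig 6 at 1.84, and the call ended with array weights (median change 0.083, adjusted p = 0.157), without pig 5 (adjusted p = 0.0911) and without pig 6, where the median change was 0.01 and the test pointed down (adjusted p = 0.639). Without pig 6 the mean change was 0.0095 for the list, 0.16 for KCNMB1, 0.16 for PLN, 0.10 for MYL9 and 0.092 for HSPB6. Between pigs in period 2 alone, MYL9 stood at -0.081 and HSPB6 at -0.030, and with pigs 5 and 6 left out HSPB6 stood at -0.0015. Immediate early genes were called lower (-0.19 ± 0.60, SD over pigs; camera adjusted p = 0.0245, adjusted p = 0.569 with an estimated correlation), with NR4A3 at -0.95, NR4A2 at -0.55, BTG2 at -0.49 and EGR2 at -0.37. Leaving out any of pigs 3, 5, 6, 7, 9 and 10 ended this call, with adjusted p-values of 0.0827, 0.116, 0.213, 0.0513, 0.0735 and 0.104, and cyclic loess (0.0633), array weights (0.0552) and the filter on intensity (0.0513) did so too. Without pig 6 the mean change was -0.048 for the list, -0.59 for NR4A3, -0.26 for NR4A2, -0.29 for BTG2 and -0.23 for EGR2, and without pig 2 it was -0.31 for the list. Between pigs in period 2 alone, NR4A2 stood at 0.083 and BTG2 at 0.036.

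Markers of goblet cells (0.07 ± 0.26, SD over 10 pigs), crypt stem cells (0.04 ± 0.14), fibroblasts (0.04 ± 0.43), red blood cells (0.06 ± 0.49), enteric neurons and glia (0.01 ± 0.20), mast cells (-0.04 ± 0.24) and neutrophils and eosinophils (-0.18 ± 0.69) were not called, with camera adjusted p-values from 0.104 to 0.841. For endothelial markers the median (0.03) and the mean (0.00078) were positive while camera's direction was down (adjusted p = 0.841). Ribosomal proteins (-0.02 ± 0.10), cholesterol biosynthesis (-0.04 ± 0.29), clock genes (-0.06 ± 0.08) and fatty acid and triglyceride synthesis (0.02 ± 0.21) were not called either, with adjusted p-values from 0.23 to 0.841. Of the 16 lists not called, leaving out some 1 pig moved the mean of 14 by over 1.5 times or turned its sign, and turned the sign of 10. The mean ranged from -0.26 (without pig 1) to -0.038 (pig 9) for neutrophils and eosinophils, from -0.026 (pig 6) to 0.13 (pig 9) for fibroblasts, and from -0.058 (pig 7) to 0.16 (pig 6) for red blood cells. It ranged from 0.020 (pig 9) to 0.11 (pig 8) for goblet cells, from 0.011 (pig 9) to 0.057 (pig 4) for crypt stem cells, from -0.039 (pig 7) to 0.038 (pig 6) for enteric neurons and glia, from -0.081 (pig 8) to 0.0054 (pig 1) for mast cells, and from -0.020 (pig 1) to 0.026 (pig 8) for endothelium. For ribosomal proteins the ends were -0.046 (pig 6) and -0.0045 (pig 5), for cholesterol biosynthesis -0.080 (pig 6) and 0.0089 (pig 7), and for fatty acid and triglyceride synthesis -0.036 (pig 6) and 0.041 (pig 8). The neutrophil and eosinophil list was called lower without pig 1 (adjusted p = 0.0033) or pig 4 (0.024), oxidative phosphorylation higher without pig 4 (0.024) or pig 5 (0.00267), and fibroblast markers higher without pig 7 (0.0361) or pig 9 (0.00285). Likewise, ribosomal proteins were called lower without pig 6 (0.0083) and cholesterol biosynthesis lower without pig 10 (0.0255). Neutrophils and eosinophils (median change -0.60, adjusted p = 0.00305) and ribosomal proteins (0.0318) were called lower in period 1 alone, and fibroblast markers higher in period 2 alone (median change 0.20, adjusted p = 0.000162). With muscle and fibroblast covariates, ribosomal proteins were called lower (0.0302).

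**Figure D2:**
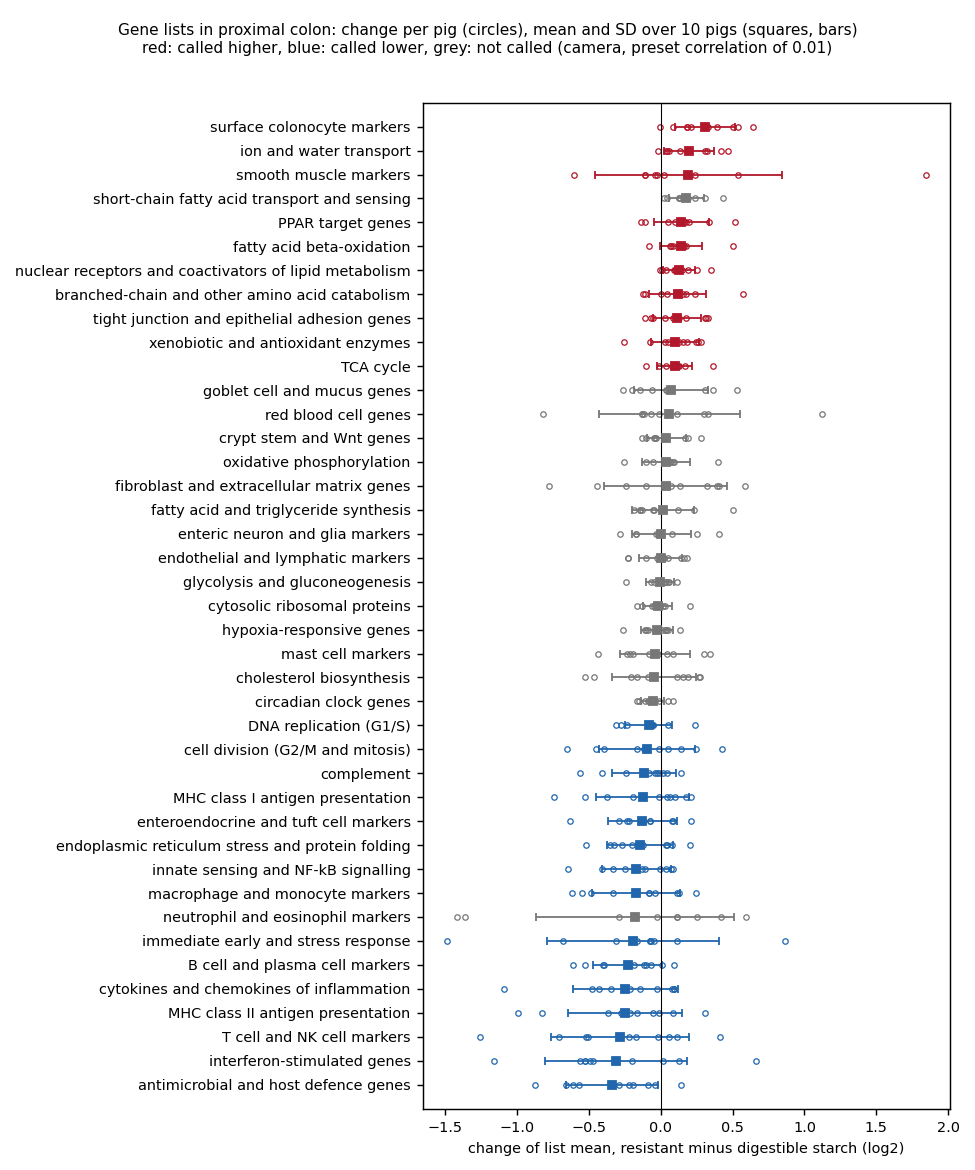
Change in the mean log2 level of each of 41 gene lists between resistant and digestible starch (x axis, log2), with a circle per pig, a square for the mean of 10 pigs and a bar for the SD. Surface colonocyte markers had the highest mean (0.31) and antimicrobial and host defence genes the lowest (-0.34), and 1 pig stood at 1.84 for smooth muscle markers; colours mark camera calls at a preset correlation, of which 0 held with an estimated one.

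The comparison of periods asked whether the tissue differed between the second and the first biopsy, 2 weeks of age and 1 earlier biopsy apart. Immediate early genes, which respond within minutes to handling, injury and growth factors, fell in period 2 by a mean of 0.33 on the log2 scale with an SD of 0.52 over 10 pigs (camera adjusted p = 3.03e-08, adjusted p = 0.699 with an estimated correlation). Without pig 6 the mean change was -0.20. Of 20 members 7 fell adjusted over the list alone. Among them were CTGF, by 0.65, CYR61, by 0.76, FOS, by 0.92, EGR1, by 0.65, and JUN, by 0.30. Enteric neuron and glia markers fell by 0.14 with an SD of 0.14, in 8 of 10 pigs (camera adjusted p = 0.000574, adjusted p = 0.392 with an estimated correlation), with 0 of 19 members past the threshold adjusted over the list alone.

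For single features, limma called 0 of 26596 between periods, with a smallest adjusted p of 0.999, and 893 had an unadjusted p under 0.05 where 1330 were expected by chance. The smallest unadjusted p-values with a lower level in period 2, none past the threshold, belonged to CTGF, the cytokine IL18 (-0.53 ± 0.13, SE; lower in 10 of 10 pigs), CYR61, ZBTB22 (-0.29) and the calcium-binding S100G (-0.99). With a higher level they belonged to CCL28 (0.37 ± 0.08), HES7 (0.24), ERICH2 (0.27), POPDC3 (0.29) and TTC32 (0.28).

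Camera called 14 lists between periods, 4 higher and 10 lower in period 2, of which 0 held with an estimated correlation (smallest adjusted p = 0.392); fry called 0 and exact sign flips 0. Of these calls 2, the immediate early and the enteric neuron lists, held when each pig was left out in turn. The lists called higher were oxidative phosphorylation (0.07 ± 0.16, SD over 10 pigs), ribosomal proteins (0.05 ± 0.09), cholesterol biosynthesis (0.10 ± 0.28) and the TCA cycle (0.06 ± 0.14). Called lower were DNA replication (-0.06 ± 0.17), B cells (-0.11 ± 0.32), endothelium (-0.07 ± 0.13), interferon-stimulated genes (-0.09 ± 0.58), neutrophils and eosinophils (-0.29 ± 0.64), red blood cells (-0.27 ± 0.41), macrophages (-0.07 ± 0.35) and cytokines (-0.10 ± 0.43). Their adjusted p was 0.699 with an estimated correlation in each case. Leaving out some 1 pig moved the mean of 12 of the 14 lists by over 1.5 times or turned its sign. Without pig 6 it was 0.031 for oxidative phosphorylation, 0.027 for ribosomal proteins, 0.032 for the TCA cycle, -0.18 for neutrophils, -0.023 for macrophages, -0.053 for interferon-stimulated genes and 0.0068 for cytokines. Without pig 5 it was 0.063 for cholesterol biosynthesis, -0.097 for DNA replication, -0.17 for B cells, -0.23 for interferon-stimulated genes, -0.14 for macrophages and -0.16 for cytokines. Without pig 1 it was -0.032 for DNA replication, -0.053 for B cells, -0.043 for interferon-stimulated genes and -0.0082 for macrophages. Without pig 9 it was -0.037 for DNA replication, -0.051 for interferon-stimulated genes, -0.17 for neutrophils, -0.040 for macrophages and -0.061 for cytokines. Pigs 3, 4, 7 and 10 moved DNA replication (-0.036 without pig 3), interferon-stimulated genes (-0.032 without pig 3, -0.047 without pig 4, -0.16 without pig 10), B cells (-0.063 without pig 4), cholesterol biosynthesis (0.055 without pig 7) and red blood cells (-0.17 without pig 7). The number of the 14 calls that held was 11 without pig 1, 6 without pig 2, 9 without pig 3, 11 without pig 4, 9 without pig 5, 6 without pig 6, 9 without pig 7, 13 without pig 8, 9 without pig 9 and 13 without pig 10.

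The comparison of diet orders asked whether pigs that started on resistant starch differed, over both biopsies, from pigs that started on digestible starch, 5 pigs against 5. limma called 0 of 26596 features (smallest adjusted p = 0.721), with 1257 at an unadjusted p under 0.05 where 1330 were expected by chance. Without pig 8, 6 features were called. The same contrast holds carry-over from the first diet, a diet effect that differs between the 2 periods, and differences between the 2 groups of pigs. These cannot be told apart here. It compares 5 pigs with 5, so a count of 0 does not show that the diet effect was alike in both periods. For the 41 list means, an exact permutation test of the order, added after the data were seen, gave a smallest adjusted p of 0.542, for antimicrobial genes (difference -0.20, exact p = 0.0238), immediate early genes (-0.33, exact p = 0.0317) and neutrophil markers (-0.37, exact p = 0.0397).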

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

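The patterns weighed here, the list of common epithelial genes, the final rules for reading that test and the T cell test without 2 pigs, and the relabelling counts of features past the adjusted threshold were chosen only after results had been seen.

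Among 71 sets of 10 per-pig diet changes, 41 for lists and 30 for genes, 7 held a pig far from the others, all of them lists. Chance flags about 1 in 20 groups, and lists measured in the same biopsies are not independent. Pig 6 stood apart in 6 of them. Its change was 0.402 for oxidative phosphorylation (next pig 0.0934), 0.5 for fatty acid beta-oxidation (0.179) and 0.573 for amino acid catabolism (0.238). It was 0.206 for ribosomal proteins (next pig 0.0321), -1.09 for cytokines and chemokines (-0.478) and 1.84 for smooth muscle markers (0.539). Pig 9 stood apart for glycolysis, at -0.239 against -0.0639 in the next pig.

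Other splits of the pigs were drawn by relabelling within pigs, with 5 pigs kept in each order, 100 of the 126 possible. For diet, 3 of the 100 splits, the real one included, gave as many features at an unadjusted p under 0.05 as the real 2643. The highest other split gave 2984. For diet lists, 4 of 100 reached the real 25, with 28 as the highest other and a median of 13 over the other splits. Both shares lay under the limit of 5 in 100 set for these tests. They are not adjusted over the relabelling tests, and not all possible splits were drawn. Counts this large were thus uncommon under relabelling, but chance was not excluded. For period, 76 of 100 splits reached the real 893 features (highest other 3134) and 42 of 100 the real 14 lists (highest other 22), so chance was not excluded. For diet order, 43 of 100 reached the real 1257 features (highest other 3792), and chance was not excluded. For features past the adjusted threshold the real count was 0 in all 3 comparisons, which any split reaches (100 of 100), so these counts decide nothing; the highest other splits gave 2 for diet, 0 for period and 9 for diet order.

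The first pattern weighed was the rise of surface colonocyte markers on resistant starch. Without the 2 pigs with the largest rise, pigs 5 and 1, the mean change was 0.236 ± 0.164 (SD, n = 8, exact sign-flip p = 0.0156). Of these 8 pigs 7 were higher, so the rise was not confined to those 2 pigs. The exact sign-flip p over all 10 pigs, 0.00391, was already known, so the p over 8 is no independent support. The colonocyte change exceeded the mean of the goblet, fibroblast, endothelial and enteric neuron lists in 9 of 10 pigs. The difference was 0.278 ± 0.194 (SD; exact sign-flip p = 0.00781), and the mean change of those lists was 0.0283 ± 0.156. The colonocyte list was picked for its rise after results had been seen, and those lists were not called, so the difference partly restates that choice. Smooth muscle markers, called higher, were left out of the comparison. A lower share of immune cells that raises all other cell types alike was thus not decided by this test. With smooth muscle and fibroblast means as covariates the median change was 0.243, against 0.251 without them. An effect of the diet on these cells or on their number may remain, as a hypothesis; the share of surface epithelium in each biopsy was not measured, and in period 2 alone the call ended (adjusted p = 0.085).

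The second pattern was the fall of T cell and NK cell markers. Smooth muscle and fibroblast covariates left the median change at -0.276, against -0.296 without them, which argues against muscle and connective tissue content as the whole cause. Without the 2 pigs with the largest fall, pigs 1 and 5, the mean change was -0.106 ± 0.316 (SD, n = 8; exact sign-flip p = 0.359), with 5 of 8 pigs lower. The prediction written for this test counted an exact p of 0.05 or more for a few pigs, and 0.359 met it. The requirement that the exact p over all 10 pigs be under 0.05 was added after the value was seen. That p was 0.0898 and was already known, so the test decides little. A few pigs may account for much of the fall but were not shown to. Lymphoid follicles caught by some biopsies and an effect of the diet both stay open, neither of them tested directly.

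The third pattern was the rise of fatty acid beta-oxidation genes. Without the 2 pigs with the largest rise, pigs 6 and 5, the mean change was 0.0932 ± 0.0791 (SD, n = 8, exact sign-flip p = 0.0312). Of these 8 pigs 7 were higher, so the rise was not confined to those 2 pigs. The list was picked for its rise in the same pigs, so the p over 8 is no independent support. Over all 10 pigs the exact sign-flip p was 0.00781, and 0.0641 adjusted over lists. More epithelium in the biopsy stays open: 10 of 12 genes common to colonic epithelial cells were measured, 2 of them also members of a fixed list, and their mean change was 0.0755 ± 0.135 (exact sign-flip p = 0.113). The beta-oxidation change exceeded theirs by 0.067 ± 0.254 (exact sign-flip p = 0.514), so the 2 cannot be told apart with this spread. The prediction written for this test would have counted that value for the epithelial explanation; the requirement that the epithelial genes themselves rise was added after the value was seen.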

How the results depend on the processing

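Named rows only, pigs 5 and 6 left out together, exact sign flips and older symbols of ATP synthase subunits were chosen after seeing the data; the other alternatives were planned. Where a count differed, the cause was not tested, except that single periods and left-out pigs use fewer arrays and that the list tests ask different questions.

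The fit is paired, with pig as the replicate block. With no replicate block limma called 0 features for diet (smallest adjusted p = 0.0797) and camera 24 lists, and 13 lists for period. It ended the calls of xenobiotic enzymes for diet (adjusted p = 0.0822) and interferon-stimulated genes for period (0.0965) and changed no other list call; pig as a random effect ended the same calls (0.0748 and 0.0793). The number of features called for diet, 0 in the main setting, was 6 with pig as a random effect, 1 with muscle and fibroblast covariates, 2 in period 1 alone, 1 with pigs 5 and 6 left out, and 0 to 1 when each pig was left out, with the 1 found without pig 6. For diet order it was 0 to 6 when each pig was left out, with the 6 found without pig 8.

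Of the 25 diet lists called, period 2 alone gave 13, of which 11 were among the 25. An estimated correlation gave 0, fry 1 and exact sign flips 4, of which 3 were among the 25. Leaving out each pig gave 21 to 26. Of the 14 period lists called, a minimum interquartile range of 0.2 gave 9 and array weights gave 8, while an estimated correlation, fry and exact sign flips gave 0 each, and leaving out each pig gave 6 to 17. Muscle and fibroblast covariates ended the diet calls for amino acid catabolism (adjusted p = 0.119), xenobiotic enzymes (0.0567), enteroendocrine cells (0.232), smooth muscle (0.7) and immediate early genes (0.0942). Period 1 alone ended those for interferon-stimulated genes (0.0513), complement (0.0513), ion and water transport (0.0515), amino acid catabolism (0.0515), MHC class I (0.112), cell division (0.15) and xenobiotic enzymes (0.875). With pigs 5 and 6 left out, those of amino acid catabolism (0.0901), MHC class I (0.346), enteroendocrine cells (0.0666), smooth muscle (0.118) and immediate early genes (0.376) ended. For period, cyclic loess ended the calls of the TCA cycle (0.0803), ribosomal proteins (0.0602) and cytokines (0.0524), the mean of all rows of a gene that of the TCA cycle (0.0575), and the filter on intensity those of cytokines (0.084) and macrophages (0.0637), the latter also ended by the filter on the dimmest 25% (0.0595). The interquartile filter ended those of ribosomal proteins (0.529), cytokines (0.0934), macrophages (0.0934) and endothelium (0.075). Array weights ended those of cholesterol biosynthesis (0.281) and of the TCA cycle, oxidative phosphorylation, cytokines, neutrophils and red blood cells (0.0933 each). New period calls were xenobiotic enzymes lower with cyclic loess (0.0385), and T cells and innate sensing lower with muscle and fibroblast covariates (0.0394 each).

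Some list medians turned sign, mostly in lists that were not called. For diet 35 of 1146 values under alternatives did so, 6 of them in 3 called lists (smooth muscle, immediate early and enteroendocrine markers), and for period 60 of 981, 3 of them in 3 called lists. Camera's direction reversed, with a call in the main setting or the alternative, in 6 diet and 3 period values. The diet median of smooth muscle markers, 0.20 in the main setting, was 0.0066 with muscle and fibroblast covariates, with camera's direction down; these covariates include that list, so the value follows from the construction. It was -0.0275 in period 2 alone, -0.039 with pigs 5 and 6 left out and 0.012 to 0.30 when each pig was left out. For enteroendocrine markers it was 0.033 with those covariates. In period 2 alone the diet median was 0.086 for immediate early genes and -0.0029 for endoplasmic reticulum stress. For period, leaving out each pig gave medians of -0.071 to 0.13 for T cells, -0.054 to 0.071 for cell division and -0.14 to 0.15 for smooth muscle. Of the diet list values, 1046 kept both the sign of the median and the side of the threshold, 52 lost the call and 13 gained one; for period these were 842, 63 and 20. Of 3324 values of named genes for diet, 3320 kept their side of the threshold and 4 gained a call, while 15 turned sign, 11 of them in period 2 alone and 2 in period 1 alone. Period 2 alone also ended the diet call for amino acid catabolism (adjusted p = 0.101). Median centring, repeated quantile normalization and cyclic loess moved the median feature by at most 0.0056.

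The TCA cycle list had too few members left under the interquartile filter, and the red blood cell list under both filters on dim features, so these gave no value. Leaving period out gives no period value, so that alternative was not run for period. Signal over background is not given with these values, so how far dim rows limit the calls is open.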

Other observations

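The members of the hypoxia list named here, the goblet and crypt members, and the test of SLC16A1 against SLC5A8 were chosen only after their values had been seen.

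Hypoxia-responsive genes moved in both directions on resistant starch. The list was not called (camera adjusted p = 0.153), but of 21 members 3 rose and 5 fell adjusted over the list alone. CA12, a membrane carbonic anhydrase, rose by 0.84 ± 0.19 (SE) in 10 of 10 pigs, ANGPTL4 by 0.61 ± 0.17 and the growth factor VEGFA by 0.28 ± 0.09. The glycolytic enzyme HK2 fell by 0.53, PDK1, a kinase that restrains pyruvate oxidation, by 0.29, ERO1A by 0.23, ANKRD37 by 0.19 and KDM3A by 0.17. With older symbols of ATP synthase subunits added, the oxidative phosphorylation list had 35 measured members and a median change of 0.04 (camera adjusted p = 0.0741).

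Goblet cell and crypt genes held members with opposite signs, none of them past the threshold adjusted over the list alone. The mucin MUC2 stood at -0.29 ± 0.13 (SE) and SPINK4 at -0.30 ± 0.10, while RETNLB, a goblet cell secretory protein, stood at 0.64 ± 0.18 and CLCA4 at 0.67 ± 0.25. Among crypt and Wnt genes, AXIN2, a Wnt target, stood at 0.41 ± 0.11 in 9 of 10 pigs and CD44 at 0.22 ± 0.07 in 10 of 10, against -0.21 ± 0.08 for OLFM4.

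The change of SLC16A1 exceeded that of SLC5A8 by 0.941 ± 0.614 (SD, n = 10) in 10 of 10 pigs, with an exact sign-flip p of 0.00195, the smallest that 10 pigs allow. The test was written after both changes had been seen, on the genes that showed the difference, so it restates that difference and decides nothing about whether both transporters follow the diet alike. Between pigs, SLC16A1 stood at 0.83 and SLC5A8 at -0.96 in period 1 alone, and at 0.42 and 0.33 in period 2 alone.

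A link between the fall of T cell markers and other lists was tested over the 10 pigs, as a family of 3 relations with 100000 resamples each. T cell and colonocyte changes had r = -0.641 (permutation p = 0.0434, adjusted p = 0.13) and rho = -0.515 (permutation p = 0.133, adjusted p = 0.216), and r = -0.622 without pigs 1 and 8, the 2 farthest from the median. The raw p met the prediction that both lists may be sides of tissue composition, but neither value passed after adjustment. T cell and B cell changes had r = 0.501 (permutation p = 0.139, adjusted p = 0.197) and rho = 0.418 (permutation p = 0.231, adjusted p = 0.231). Without pigs 1 and 8 that r was 0.0518, so the relation rests on those pigs and a shared loss of lymphoid tissue could not be decided. T cell and interferon-stimulated changes had r = 0.442 (permutation p = 0.197, adjusted p = 0.197), rho = 0.503 (permutation p = 0.144, adjusted p = 0.216) and r = 0.42 without those pigs.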
